A study of Mus musculus with 6 samples.

How the data were processed

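RNA from the hippocampus of C57BL/6 mice at postnatal day 7 was measured on 6 microarrays for circular RNAs (circRNAs), RNAs whose ends are joined by back-splicing. Per the labels, 3 samples came from mice exposed to 3% sevoflurane, an inhaled anaesthetic, for 4 h without a break, and 3 from mice that were not exposed. Per the labels' protocols, total RNA was digested with RNase R, an exonuclease that degrades linear RNA and leaves circles, and the remaining RNA was amplified with random primers into Cy3-labelled cRNA. How complete the digestion was is not given in the sources used here, and probe signals reflect both the amount of an RNA and how much of it outlasted the enzyme. The labels do not say whether each sample was a separate animal or a pool, so p-values measure only the spread between these samples, which may be technical.

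The deposited scanner files hold intensity values of 15712 spots per array, written by Agilent Feature Extraction 11.0.1.1 for 1 colour, per the file headers. Their processed signal is an intensity after the software's background subtraction. The deposited value table holds log2 values; per the submitters' processing notes limma was used, with no version given in the sources used here. Set against the scanner files, each column of the table correlated with log2 of the median spot signal without background subtraction at r of 0.999 or above across probes, and column medians lay between 5.43 and 5.45, so the scale is log2 and the columns are set to nearly the same level; how they were normalised stays unknown. The table held 14218 of the 14236 circRNA probes of the scanner files, and the other 18 were not used in fits on it.

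The values reported here are log2 of the processed signal minus the 75th percentile of the array's circRNA probes; where signals are given on the linear scale they are multiples of that percentile. Control spots were left out, outlier spots marked by the scanner software were set to missing (39 values among circRNA probes), and spots of a probe were averaged. A circRNA probe was tested where it was well above background, by the software's own mark, on 3 or more of the 6 arrays. Groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, sevoflurane minus control, with Benjamini-Hochberg adjustment and a threshold of 0.05 (two-sided). A looser screen took circRNAs at unadjusted p under 0.05 and a change of 1.5-fold or more. Numbers of probes well above background were compared with a two-sided exact permutation test, whose smallest p with 3 arrays against 3 is 0.1. Where a probe was not well above background on any array of a group, the ratio is a bound: the mean of the brighter group against the mean, per array, of the higher of the lowest signal among probes well above background and the probe's own signal, all on normalised log2 values.

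Outside the circRNA set, 79 probes were spotted 10 times on each array: 50 for linear transcripts, 14 circRNA controls and 15 custom probes without a named target. Comparing these, and grouping the linear genes by what they do, was decided after the files had been seen. Of the 50 linear probes, 44 were named by matching their accession, without versions, to RefSeq transcripts of the GRCm38.p6 annotation. A replicated probe counted as measured on an array where at least 50% of its spots were well above background, and was tested where it was measured on 3 or more arrays. The values of 1 linear gene are not reported here. A linear probe cannot tell a linear transcript from a circle that holds the same exon.

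The other choices were made before the data were examined, among them the rule for naming circRNAs: in each direction the 12 with the smallest unadjusted p among those past the adjusted test, with 1.5-fold or more and groups that do not overlap, filled from those not past it. Because the files do not pair circRNA probes with host genes, only 2 identifiers in each direction are printed, those with the smallest unadjusted p, and the tests planned on 25 lists of host genes and on classes of circRNA were not run. The alternatives were normexp background correction with an offset of 50, quantile and median scaling, a percentile over probes measured on all arrays, the deposited log2 table, stricter and no filters, limma's trend and robust options together, array weights, the replicate number as a block, and leaving out each array. The planned normexp on mean spot signals used median spot signals, since the scanner files used here hold no mean. All 6 arrays shared 1 scan, so no slide or scan block applied; the slide row as a block, and row 1 alone, and the trend and robust options each alone, were added after the files had been seen. The number of arrays limits the precision.

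The fit was tested on simulated data with the means and spreads of 11921 circRNA probes, of which 200 were changed between the groups, in 5 runs per fold size. Noise was drawn independently for each probe and array. Deviations shared between real arrays were left out, so the recovered shares may not hold for the real data. Of the probes changed 1.5-fold, 0% passed the adjusted test and 44.4% passed the screen. Of those changed 2-fold, 48.4% passed the adjusted test, and of those changed 4-fold, 93.8%.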

Results

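The expression of circRNAs in the hippocampus was measured at postnatal day 7 in mice exposed to 3% sevoflurane for 4 h (n = 3 arrays) and in mice without exposure (n = 3 arrays). Each array carried 14236 circRNA probes. Between 11509 and 12077 of them were well above background on a single array, 10635 (74.7%) on all 6 arrays, and 1478 on none. The number averaged 11705 ± 322 (SD, n = 3) in the sevoflurane group and 11775 ± 216 (SD, n = 3) in the control group, a difference smaller than the spread within groups (exact permutation test, p = 0.9). The 75th percentile of the signal ranged from 51.7 to 80.2 between arrays, with the highest value in control 1, and no circRNA spot was saturated.

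The comparison of the groups asks which circRNAs differ after neonatal sevoflurane exposure. Of the 11957 circRNAs tested, 0 were higher and 0 were lower in the sevoflurane group at an adjusted p under 0.05 (limma with Benjamini-Hochberg adjustment, smallest adjusted p = 0.332). At an unadjusted p under 0.05, 434 circRNAs were higher and 432 were lower, 866 in all, where 598 are expected by chance. The total was 2079 without control 2, 842 without sevoflurane 3 and 786 without sevoflurane 1. It was 552 without control 3, 592 without control 1 and 597 without sevoflurane 2, at or below the number expected by chance. With a change of 1.5-fold or more in addition, 182 were higher and 205 lower. The median log2 fold change was -0.01, which the scaling itself holds near 0, and the central 95% of values lay between -0.59 and 0.54. For 10834 circRNAs (90.6%) the 95% confidence interval lay within 2-fold in either direction, and for 5800 (48.5%) within 1.5-fold. All 3 sevoflurane arrays lay above all 3 control arrays for 716 of the 11921 circRNAs with complete values, and below them for 675, together 11.7% where chance gives 10%.

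**Figure D1:**
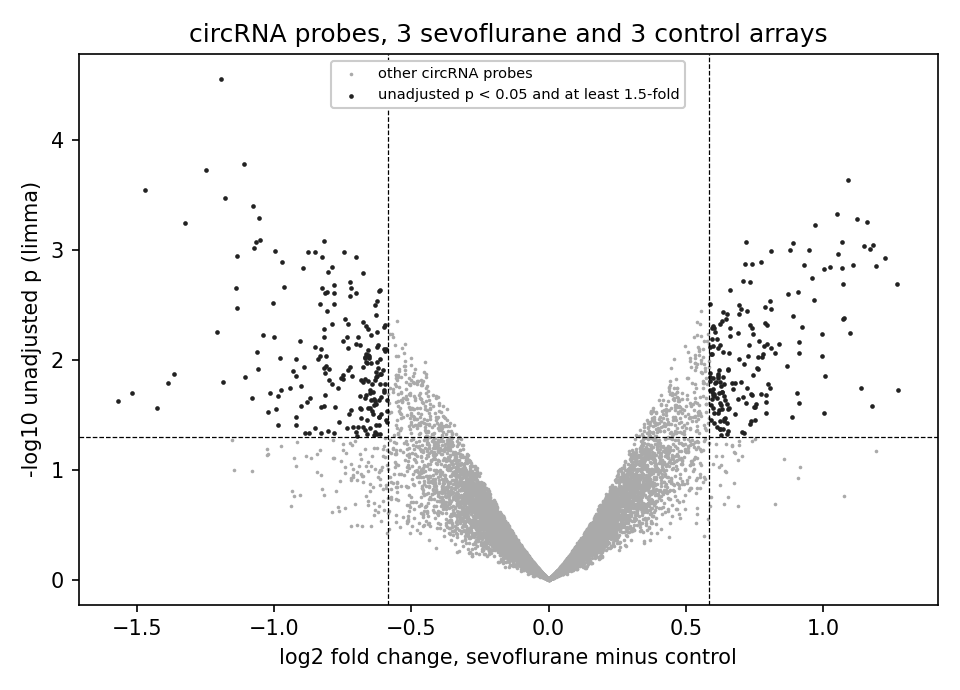
Unadjusted p (limma, on a -log10 scale) against log2 fold change, sevoflurane minus control, for the 11957 circRNA probes tested, 1 point per probe. Black points are the 182 higher and 205 lower circRNAs at an unadjusted p under 0.05 and 1.5-fold or more, dashed lines mark these limits, and no point passes an adjusted p of 0.05.

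The number past this screen differed by over 1.5 times between settings. Without control 2 it was 442 higher and 521 lower, with 0 past the adjusted test in either direction. In the deposited value table it was 62 higher and 27 lower, so that 69.7% of the screened circRNAs were higher, compared with 47.0% in the processed signals. With normexp it was 30 higher and 17 lower (63.8% higher). All sevoflurane arrays lay in row 1 of the slide together with control 1, whereas row 2 held controls 2 and 3. Both the fit with the slide row as a block and the fit within row 1 therefore set the sevoflurane arrays against control 1 alone, which is assumed to vary like the other arrays, and give the same fold changes. In both, 0 circRNAs passed the adjusted test, and the screen gave 524 higher and 410 lower with the block and 633 higher and 537 lower within row 1.

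The 24 circRNAs taken by the naming rule, 12 in each direction, did not pass the adjusted test (adjusted p from 0.332 to 0.380). Log2 fold changes of the 12 on the higher side ranged from 0.72 to 1.18, and 10 of these circRNAs were well above background on all 6 arrays. The 12 on the lower side ranged from -1.47 to -0.82, with 3 well above background on all arrays and 5 not well above background on any sevoflurane array. ASCRP4001844 had a normalised log2 signal of 0.86 ± 0.06 (SD, n = 3) in the sevoflurane group and -0.23 ± 0.31 (SD, n = 3) in the control group, a log2 fold change of 1.09 (SE 0.18; limma, adjusted p = 0.380). ASCRP4002961 was well above background on the 3 sevoflurane arrays and on none of the controls. The bound on its ratio, sevoflurane over control, was 1.52 in the processed signals and was not tested. Its fitted log2 fold change was 1.05 (limma, adjusted p = 0.380). ASCRP4008582 and ASCRP4012229 were well above background on the 3 control arrays and on no sevoflurane array. The bounds on their ratios, control over sevoflurane, were 1.65 and 1.21 in the processed signals, respectively, and were not tested. Their fitted log2 fold changes were -1.19 and -1.11 (limma, adjusted p = 0.332 and 0.380). With normexp the fitted log2 fold changes of ASCRP4002961, ASCRP4008582 and ASCRP4012229 came to 0.18, -0.06 and -0.04, and that of ASCRP4001844 to 0.61. In the deposited values they were 0.22, -0.32, -0.28 and 0.85, in the same order. The bounds therefore hold for the processed signals alone.

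Numbers of circRNAs seen in a single group fell within the range of other sets of arrays. A total of 16 circRNAs were well above background on all sevoflurane arrays and on no control array, with a median bound of at least 1.35-fold and a highest of at least 1.82-fold. In the opposite direction there were 21 circRNAs, with a median bound of at least 1.31-fold and a highest of at least 1.68-fold. Of both sets, 0 passed the adjusted test, and the other 18 sets of 3 arrays gave between 0 and 40 such circRNAs each.

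The arrays also carried probes for linear transcripts, many of them matched to a named gene, here read in RNA digested with RNase R. How much of a probe's signal came from its named gene was not tested. Of the 50 probes, 34 were measured on 3 or more arrays and tested, 30 of them with a gene symbol. None of the 34 passed the adjusted test over the 61 replicated probes (limma, smallest adjusted p = 0.463), or when adjusted over the linear probes alone. An unadjusted p under 0.05 was found for 2, Chgb and a probe without a matched symbol (log2 fold change 0.41). That count of 2 was 7 without control 2, 3 without sevoflurane 1, 1 without control 3, and 0 without control 1 or without sevoflurane 2. The probe without a symbol read 0.685 with sevoflurane and 0.515 in controls. Its log2 fold change was as low as 0.19 over the other scalings and normexp. A probe whose name marks it as negative had a similar level and direction (0.664 with sevoflurane and 0.545 in controls). In 22 of the 34 the fold change was below 0 and in 12 above it, with a median log2 fold change of -0.12. Of the 34 probes, 25 in control 1 and 29 in control 3 lay above their 6-array mean, but 9 in control 2 and between 13 and 17 on the sevoflurane arrays. The sign turned under another scaling or normexp in 9 of the 34. Among the genes described below, Chgb, Cpt1a, Acaa2, Gsta4, Atg3, E2f1 and Prdx2 had lower mean signals than 2 probes whose names mark them as negative. Lhx1 lay below both of these probes with sevoflurane (0.504 against 0.664 and 0.635) and between them in controls (0.562 against 0.545 and 0.581).

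The probe for Actb, which encodes the cytoskeletal protein beta-actin, had a mean signal of 4.45 ± 1.58 (SD, n = 3) times the array's 75th percentile with sevoflurane and 7.26 ± 2.89 (SD, n = 3) in controls. Its log2 fold change was -0.67 (SE 0.36; limma, adjusted p = 0.709), within the spread of the groups. Single arrays ran from 3.13 to 6.21 with sevoflurane, and the controls read 9.02, 3.92 and 8.82, so that control 2 lay with the sevoflurane arrays. With each array left out in turn the log2 fold change of Actb lay between -1.06, without control 2 (limma, adjusted p = 0.0817), and -0.44, without sevoflurane 3 (limma, adjusted p = 0.738). Chgb, which encodes chromogranin B, a protein of secretory granules in neurons and endocrine cells, had a log2 fold change of -0.74 (SE 0.26; limma, adjusted p = 0.463). Its probe was measured on 3 control arrays but on only 1 sevoflurane array, and with normexp the value was -0.05. Apoe, a lipid carrier made in the brain chiefly by astrocytes and a member of the astrocyte marker list, had signals of 4.99 ± 0.34 (SD, n = 3) with sevoflurane and 5.73 ± 0.21 (SD, n = 3) in controls. All 3 Apoe values were lower with sevoflurane than in any control, at a log2 fold change of -0.20 (SE 0.13; limma, adjusted p = 0.733). Of the 34 linear probes tested, 2 had groups that did not overlap, where chance gives 10% of probes.

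**Figure D2:**
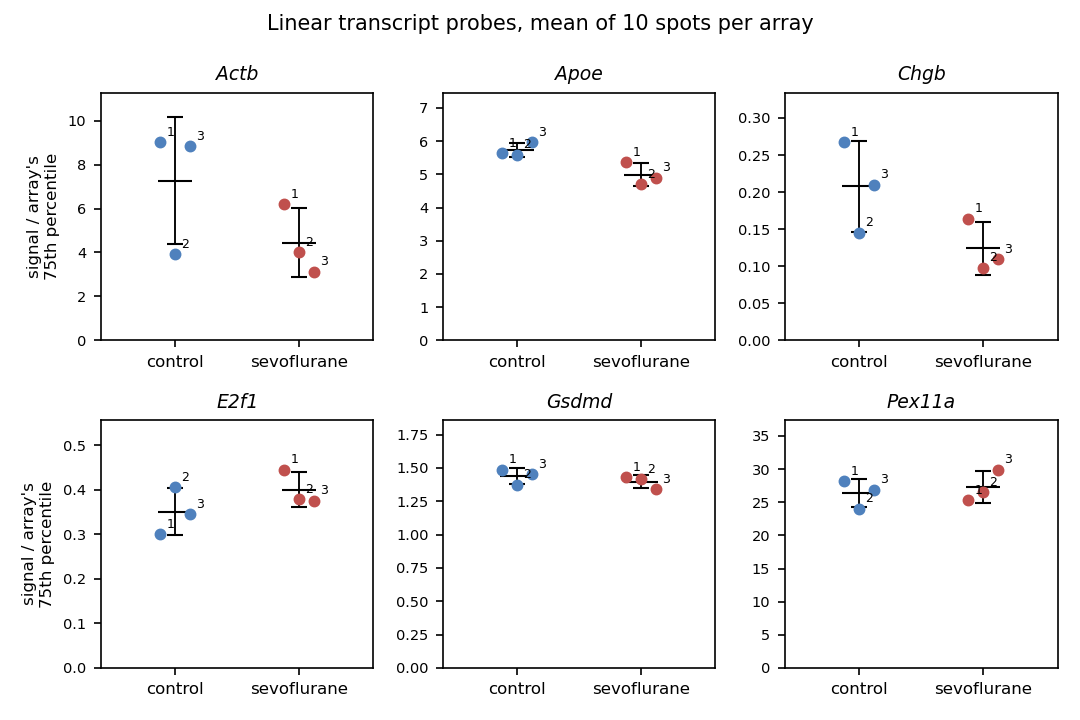
Signal of 6 linear transcript probes on each array, as multiples of the array's 75th percentile on a linear axis from 0, each point being the mean of the probe's spots on 1 array with its replicate number. Black bars give the mean ± SD of 3 arrays; for Actb, control 2 (3.92) lies apart from controls 1 and 3 (9.02 and 8.82).

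Among single genes of energy metabolism, Cpt1a, which passes long-chain fatty acids into mitochondria, had a log2 fold change of 0.01 (SE 0.16), Gamt, an enzyme of creatine synthesis, -0.03 (SE 0.17), and Gpi1, an enzyme of glycolysis, 0.00 (SE 0.17), with a sign for Gpi1 that turned with the scaling. Acaa2, a thiolase of mitochondrial fatty acid oxidation, had -0.33 (SE 0.22), which turned to 0.01 with normexp and was -0.59 without control 2, where it passed the adjusted test (limma, adjusted p = 0.0419). Pex11a, which takes part in peroxisome division, had signals of 27.3 ± 2.40 (SD, n = 3) with sevoflurane and 26.4 ± 2.09 (SD, n = 3) in controls, a difference within the spread whose sign turned with the scaling.

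Gsdmd, the pore-forming protein of pyroptosis and a member of the cell death list, had a log2 fold change of -0.04 (SE 0.13). Prdx2, which reduces peroxides, had -0.17 (SE 0.17), and Gsta4, a glutathione transferase that clears lipid peroxidation products, had -0.21 (SE 0.19), with a sign that turned with normexp. Atg3, an enzyme of autophagosome formation and a member of the autophagy list, had -0.35 (SE 0.50), likewise with a sign that turned. Among regulators of proliferation and neural fate, E2f1 had 0.20 (SE 0.16) and Lhx1 -0.15 (SE 0.18). Linear probes for Mbp (myelin), Gabrg1 (a subunit of GABA-A receptors) and Kcnn2 (a calcium-activated potassium channel), each on a gene list fixed for the circRNA tests, were not measured on any array.

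The other replicated probes have no named gene. Of 14 circRNA control probes, 7 had a fold change above 0 and 7 below it, with a median log2 fold change of -0.01. Their values ranged from -0.27 to 0.42, with 1 at an unadjusted p under 0.05 (limma) and 0 past the adjusted test. Of 13 custom probes measured, 12 were below 0, with a median of -0.18. Of these 13 probes, 11 in control 1 and 12 in control 3 lay above their 6-array mean, but 4 in control 2 and between 2 and 6 on the sevoflurane arrays. The custom probe with the smallest p read 9.81 ± 1.67 (SD, n = 3) with sevoflurane and 14.6 ± 1.83 (SD, n = 3) in controls, a log2 fold change of -0.58 (limma, adjusted p = 0.463). It passed the adjusted test with limma's trend and robust options together (adjusted p = 0.0459).

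Within the control group, controls 1 and 3 resembled each other more than control 2. Across circRNAs, which are not independent replicates, deviations from the 6-array mean correlated at 0.37 between controls 1 and 3, at -0.46 between controls 1 and 2 and at -0.38 between controls 2 and 3. Equally variable arrays that share nothing would correlate at -0.2, because the mean is taken over the same 6 arrays. Among the sevoflurane arrays these correlations ran from -0.23 to -0.02. The median SD of log2 signals was 0.22 in controls and 0.19 in the sevoflurane group, and it was larger in controls for 57.6% of circRNAs.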

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

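Alternatives on the slide row, on limma's trend or robust option alone and all those on the linear and control probes were chosen after the data were seen. At an adjusted p under 0.05 (limma), 0 circRNAs were higher and 0 lower under all 20 alternatives, with the smallest adjusted p between 0.0732 (array weights) and 0.986 (without control 1). The count past unadjusted p and 1.5-fold, 182 higher and 205 lower, moved as follows, and the cause was not tested except for the deposited values. Array weights gave 365 and 478, no filter 280 and 311 (more probes tested), probes on all arrays 125 lower (fewer tested), normexp 30 and 17, the deposited values 62 and 27, the slide row block 524 and 410, and slide row 1 alone 633 and 537, both resting on control 1 as the lone control. Leaving out each array gave 146 to 442 higher and 163 to 521 lower, with the highest counts without control 2. With the replicate block, 0 passed in either direction and the screen gave 201 and 271. No sign of pairing by the shared replicate numbers was seen. Deviations from the own group's mean, for arrays with the same number, correlated at 0.10, 0.04 and -0.11. Not every array correlated best with its own number. With 3 arrays per group this cannot exclude a pairing, which the labels neither state nor deny.

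The sevoflurane minus control difference in circRNAs well above background (-69.7) ran from -256 to 28.3 when each array was left out, turning above 0 without sevoflurane 1, sevoflurane 3 or control 3. The 4 named circRNAs kept their sign under every alternative run for them. They were chosen for groups that do not overlap, so leaving out arrays, blocks and array weights could not turn it. With normexp, ASCRP4002961, ASCRP4008582 and ASCRP4012229 came to 0.18, -0.06 and -0.04. Of the linear, control and custom probes, 1 passed the adjusted test with the trend and robust options together, and 0 with either alone. Leaving out each array gave 0 to 3, with 3 without control 2, Acaa2 and 2 custom probes. A slide or scan block did not apply, and host gene lists and circRNA classes were not run for want of host gene names. In the processed signals the median SE of the log2 fold change was 0.22 in the dimmest 25% of circRNAs and 0.18 in the brightest 25%. For normexp a different measure was taken, the median SD within groups. It was 0.099 in the dimmest and 0.161 in the brightest 25% by normexp signal. The sizes of the SE and the SD cannot be compared.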

Other observations

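The tests on the slopes by brightness, on the correlation in the brightest 25% of circRNAs, on limma's trend and robust options together and on normexp were set out before their results were seen; the others in this part were chosen after.

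Linear and custom probes were high on the same arrays. Controls 1 and 3 had the highest numbers of both linear and custom probes above their 6-array mean. The 14 circRNA control probes showed no such order, with 5 in control 1, 11 in control 3 and between 5 and 9 elsewhere. Among 15 probes whose names mark them as negative, 2 were well above background on all 6 arrays. Their mean signals were 0.664 and 0.635 with sevoflurane and 0.545 and 0.581 in controls, respectively. For both, all 3 sevoflurane values lay above all 3 control values (exact permutation test, p = 0.1, the smallest possible). What this means for fold changes of probes with a similar signal was not tested.

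Controls 1 and 3 stood apart from the other 4 arrays: the first principal component, with 39.2% of the variance, placed them at 30.1 and 20.8 and the other arrays between -18.0 and -4.69. Array brightness and background acting on dim circRNAs alone are argued against. The deviations of controls 1 and 3 correlated at 0.69 across the brightest 25% of circRNAs after quantile normalization. Other differences in brightness that reach bright circRNAs would leave such a correlation too and were not tested. The mean correlation of control 2 with controls 1 and 3 was -0.42 and with the sevoflurane arrays -0.042, which restates the pattern and leaves a part for the exposure open. More linear RNA left after RNase R in controls 1 and 3 is a candidate explanation, with at least 25 of 34 linear probes above their mean in each, against 17 or fewer on every other array. A wrong label on control 2 stays open as well: its mean correlation with the sevoflurane arrays (-0.042) and theirs with one another (-0.10) both lay above the -0.2 of arrays that share nothing, as they would with controls 1 and 3 apart for any reason.

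Fewer circRNAs passed the 1.5-fold screen in the deposited value table (89) than in background-subtracted signals (387). Quantile normalization is argued against as the reason, since applied to background-subtracted signals it left 376. Background remaining in the table's values is a candidate explanation: the slope of its fold changes on the background-subtracted ones was 0.30 in the dimmest 25% of circRNAs and 0.88 in the brightest. No biological explanation was tested.

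Among the dimmest 25% of circRNAs, 10.3% had an unadjusted p under 0.05, compared with 6.59% in the brightest 25%, a ratio of 1.56. A candidate explanation is that the test used 1 spread prior for dim and bright probes; the ratio was 0.80 with limma's trend and robust options together, 0.77 with the trend alone and 1.56 with the robust option alone. The background subtraction stays open too, with a ratio of 0.083 under normexp, whose offset also compresses the fold changes of dim probes. A stronger response of rare circRNAs to the exposure was not tested.

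The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For circRNAs past the adjusted test the real split gave 0 and the highest other split 51, a comparison in which all 10 splits reach the real count of 0 by construction. For the 1.5-fold screen the real split gave 387 and the highest other split 602, and 2 splits, the real one included, gave as many. The highest split in both counts set sevoflurane 1 with controls 1 and 3. The screen counts followed controls 1 and 3: splits with both on the same side gave 602, 387 (the real split), 361 and 306. Splits that separated these 2 arrays gave between 70 and 153. The real groups also keep controls 1 and 3 together, so the counts cannot tell the exposure from another structure of the samples.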
